A study of Homo sapiens with 7 samples.

How the data were processed

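DRIP-seq was done in RPE1 cells (p53 and puromycin-resistance double knockout, inducible Cas9), WT or CFAP20-KO, with mock or RNaseH1 treatment of DNA digested with HindIII, EcoRI, BsrGI, SspI and XbaI. The deposited tables give, per the labels, a signal in 200 bp bins from 100 kb upstream to 100 kb downstream of TSSs, TTSs and origin centres, with 3 tables per library and 7 libraries. The authors scaled each library by 1 factor whose reference is not stated, so the values are relative signal and not read counts, and no count model was used. In each library 100% of the values were, to within 0.01 of a step, whole multiples of a step between 0.0590 and 0.226. Values below 0 by rounding error were set to 0. The origin tables are labelled as made without removal of duplicate reads, and the handling of duplicates is not stated for TSSs and TTSs. The submitters name FastQC 0.11.9, Trim Galore 0.6.5, BWA 0.7.17, SAMtools 1.11, HOMER 4.8.2, STAR 2.7.7a and R 4.0.5. Coordinates are hg38. Of the 9944 genes that the authors' coordinates list, 9728 were matched by Ensembl identifier to GENCODE release 44, whose symbols are printed and differ from the deposited ones for 3262. A nascent transcription value in WT (BrU labelling over the gene body, unit not stated) was given for 6325 genes and was used only to rank them. A coordinate table of 2040 origins covers part of the 4784 origins measured, so origin positions were read from the origins' names. Genes in the tables are at least 3002 bp long, which leaves out most histone genes.

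The number of steps per bin sets the precision of each value: between 6.24% and 30.7% of TSS bins were at 0 in a library. Precision was read from the spread between libraries, and with 2, 1, 2 and 2 libraries per group the p-values measure a spread between these libraries that may be technical.

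The following choices were made before the data were examined: the windows, filter, pseudocount, tests, 18 gene lists and the rule for which genes are named. Windows ran from 1 kb upstream to 4 kb downstream of TSSs and TTSs, and 10 kb to either side of origin centres. The mean of each window over its bins was averaged over all sites for the site means, compared with an exact two-sided permutation test. For single sites, the row with the highest mean was kept per symbol (9863), windows with a mean over libraries above the median distal signal 50 to 100 kb away (0.578 at TSSs, 0.573 at TTSs, 0.632 at origins) were tested, and 10% of the median window was added before taking log2 (0.0577, 0.0546, 0.0566). This left 5060 promoters, 4585 TTSs and 1946 origins. limma 3.58.1 fitted 4 group means over the 7 libraries, with 3 residual degrees of freedom, an adjusted p (Benjamini-Hochberg) threshold of 0.05 and an infinite prior, so that each window of a comparison had the same standard error (0.48 for promoters in KO mock against WT mock, 0.59 in WT mock against WT RNaseH). The lone WT RNaseH library was assumed to vary like the other groups. A promoter was called separated when all libraries of 1 group lay beyond those of the other. Groups of 2 allow no search for outlying libraries and no count over other splits of the samples.

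The gene lists were the R-loop loci often assayed by DRIP-qPCR, R-loop processing factors, immediate early genes, cytosolic ribosomal proteins, replication-dependent histones, snoRNA host genes, spliceosome and hnRNP genes, DNA replication factors, common fragile site genes, cilium genes, p53 targets, the integrated stress response, heat shock and chaperones, oxidative phosphorylation, glycolysis, cholesterol synthesis, extracellular matrix and mesenchymal genes, and genes of other cell types expected to be silent. The 14 lists with at least 3 tested promoters were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, adjusted over the lists. The genes named are the DRIP-qPCR loci and CFAP20; at promoters in KO mock against WT mock and KO mock against KO RNaseH, the 10 highest and 10 lowest that pass and are separated, or the 5 smallest unadjusted p in each direction where fewer than 5 pass; the members of each list with the smallest p; and the 3 highest and 3 lowest TTSs and origins by the same rule. Further members of lists, the other called origins, genes near origins and genes named for the interaction or between RNaseH libraries were chosen after their values were seen. A few genes that the rule or a list names are not reported here.

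Regions of shifted distal signal were searched after the data were examined, on log2 signal 50 to 100 kb from 9365 TSSs with the trend in GC content removed. Alternatives were another scaling (distal signal, quantile), pseudocount, filter, window, limma with trend and robust, a replicate block, only the groups compared, and each library left out. Alternatives added after the data were seen were each window over its own distal signal, distal scaling with the block, sites outside the shifted regions, and leaving out both KO libraries numbered 1. On simulated data with this spread, limma called 9% of 2-fold and 80% of 4-fold changed promoters in KO mock against WT mock. There were 3 wrong calls among 5060 and 0 calls without a change. The simulated noise was independent between windows with the same SD in each, as the fit assumes, so wrong calls from unequal spread were not tested. The search for regions found 6 of 6 simulated shifts and none without a shift, on ratios with no correlation between neighbouring TSSs. Distal scaling moved the median log2 of all promoters by 0.14 in WT mock against RNaseH and by 0.12 in KO mock against RNaseH, and quantile normalization moved it by -0.10 in KO mock against WT mock, -0.35 in KO mock against RNaseH and 0.27 between the RNaseH libraries. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3. A second per-sample column in 14 of the tables was not used here.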

Results

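DNA-RNA hybrids were measured by DRIP-seq, in which the S9.6 antibody pulls down hybrids from restriction-digested genomic DNA before sequencing. The cells were RPE1, an hTERT-immortalised line of retinal pigment epithelium that lacks p53, either wild type (WT) or knocked out for CFAP20 (KO), a protein of motile cilia and of the nucleus. Mock-treated DNA carries the hybrids, and DNA treated with RNase H1, which degrades the RNA strand of hybrids, gives the background of the pulldown. There were 7 libraries: 2 WT mock, 1 WT RNaseH, 2 KO mock and 2 KO RNaseH. Each library came as a signal per 200 bp bin around 9879 transcription start sites (TSSs), 9879 transcription termination sites (TTSs) and 4784 replication origins mapped by Okazaki fragment sequencing. Every value was, to within 0.01 of a step, a whole multiple of a step specific to its library. Coverage in these steps, summed over the TSS bins, was 6.48e+07 in WT mock replicate 1, 1.62e+08 in WT mock replicate 2 and 4.07e+07 in WT RNaseH. It was 8.97e+07 in KO mock replicate 1, 1.04e+08 in KO mock replicate 2, 3.12e+07 in KO RNaseH replicate 1 and 6.60e+07 in KO RNaseH replicate 2. A read spans several bins, so these totals rank the libraries by depth and do not count reads. Values below are mean signal per bin of a window, with the SD between libraries, and the single WT RNaseH library has no error.

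The series was made to explore CFAP20 in the resolution of R-loops, and the first comparison asks how hybrids at promoters differ between KO and WT cells. CFAP20 itself was not among the measured genes, so its own locus gives no value. Mean promoter signal, from 1 kb upstream to 4 kb downstream of the TSS, was 1.04 ± 0.126 (SD, n = 2) in WT mock and 1.22 ± 0.123 (SD, n = 2) in KO mock, 16.3% higher in KO (log2 0.22). An exact two-sided permutation test did not resolve the difference (exact p = 0.667, where 0.333 is the smallest that 2 against 2 libraries can give). The profile peaked at the TSS, at 1.18 and 1.43 in the WT mock libraries and at 1.51 and 1.65 in the KO mock libraries. With a library left out the log2 difference of the means ranged from 0.10 to 0.35. The median over TSSs in place of the mean gave a log2 of -0.06, and 55.5% of TSSs had the higher mean in KO.

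**Figure D1:**
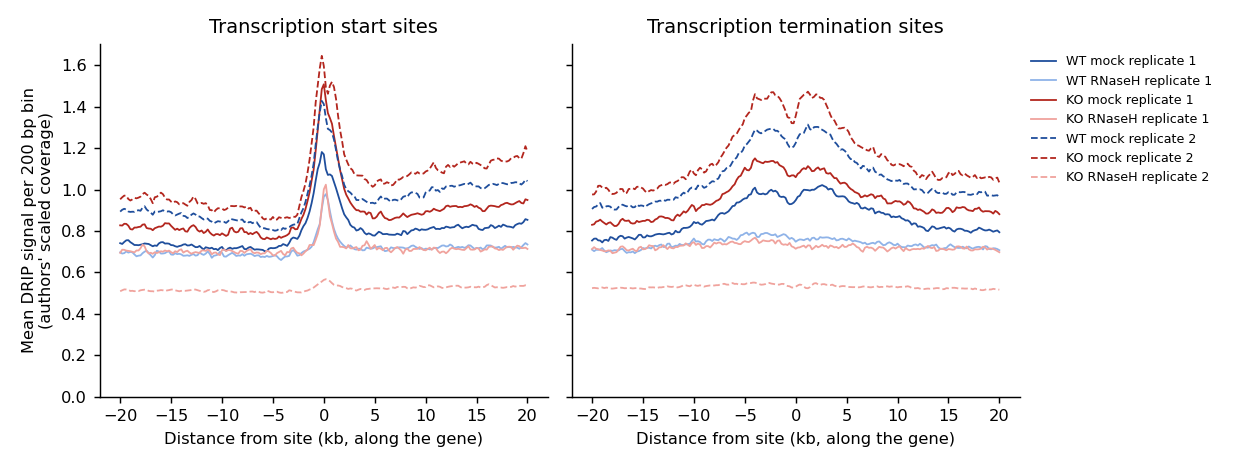
Mean DRIP signal per 200 bp bin around transcription start sites and termination sites, against distance in kb, with a line for each of the 7 libraries. At the start sites the mock libraries peak between 1.18 and 1.65 and the RNaseH libraries between 0.567 and 1.02.

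The difference was also taken by strength of transcription, without a test. Genes were split into quartiles by their nascent transcription in WT cells, measured by the authors as BrU labelling of new RNA over the gene body. In the highest quartile, 1580 TSSs, promoter signal was 2.72 ± 0.481 (SD, n = 2) in WT mock and 3.48 ± 0.595 (SD, n = 2) in KO mock, 1.28-fold higher in KO. The log2 difference was 0.02 in the lowest quartile, 0.12 in the next, 0.24 in the third and 0.36 in the highest, and -0.05 at the 3558 TSSs with no BrU value. The highest minus the lowest quartile came to 0.34, against an SD between replicates of 0.27, and it ranged from 0.11 without KO mock replicate 2 to 0.55 without KO mock replicate 1. WT mock signal rose over the same quartiles, from 0.553 to 0.930, 1.35 and 2.72. A difference that goes with signal strength therefore cannot be told apart here from a difference that goes with transcription. RNaseH libraries rose less with transcription: the highest quartile, at 1.20 in WT RNaseH and 0.853 ± 0.249 (SD, n = 2) in KO RNaseH, was 1.80 times the lowest in WT and 1.42 and 1.35 times in KO, against 4.41 to 7.2 times in the mock libraries. At the TSSs with no BrU value the RNaseH mean was above the mock mean, with 0.595 against 0.435 in WT and 0.553 against 0.422 in KO.

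**Figure D2:**
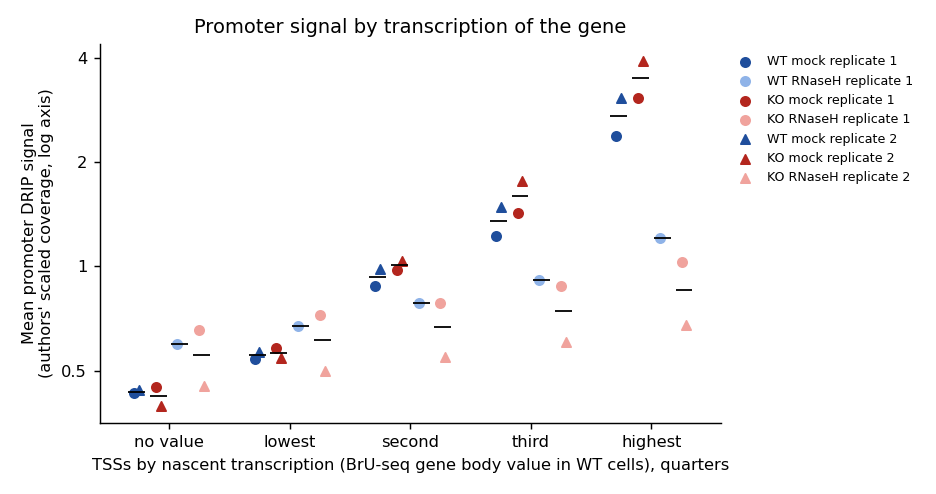
Mean promoter signal (log axis) of each library in 5 groups of genes: those with no BrU value and the quartiles of BrU signal in WT cells. A short line marks the mean of the libraries of each genotype and treatment. In the highest quartile the KO mock mean was 3.48 and the WT mock mean 2.72.

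Among single promoters, PCAT5, a long noncoding RNA gene first described in prostate cancer, was the one of 5060 that passed limma in KO mock against WT mock. Its signal fell from 1.76 ± 0.184 (SD, n = 2) in WT mock to 0.380 ± 0.225 (SD, n = 2) in KO mock, a log2 change of -2.15 with adjusted p = 0.0399. It is ENSG00000280719.1, with its TSS at position 35778302 of chromosome 10 (hg38). The RNaseH libraries differed in the same way there, with 1.64 in WT and 0.751 ± 0.276 (SD, n = 2) in KO. No promoter passed as higher, and at an unadjusted p under 0.05 there were 126 higher and 62 lower promoters. Together these 188 were below the share of promoters that this threshold gives by chance. The PCAT5 call was lost without WT mock replicate 1 (adjusted p = 1.00), WT mock replicate 2 (0.814), KO mock replicate 1 (0.682) or either KO RNaseH library (0.117 each). Of the 5060 promoters, 1652 (32.6%) had both KO mock libraries beyond both WT mock libraries, where chance gives 33.3%.

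The 5 promoters with the smallest unadjusted p in each direction held genes of several kinds, and all but PCAT5 missed the threshold. On the higher side stood CD24, a cell-surface glycoprotein (log2 1.95, adjusted p = 0.0830, 0.554 ± 0.169 in WT mock and 2.27 ± 0.161 in KO mock), and ITGA11, a collagen-binding integrin subunit (1.77, from 1.41 ± 0.644 to 4.78 ± 1.36). CAMK2N1, an inhibitor of CaM kinase II, had a log2 difference of 1.62, SRM, the spermidine synthase, 1.60, and the zinc finger gene ZSCAN18 1.58. On the lower side stood EPS8L1, a relative of the actin regulator EPS8 (-2.05, adjusted p = 0.0536, 3.10 ± 0.305 in WT mock and 0.708 ± 0.0919 in KO mock), and TBL2 (-1.74), ENSG00000238176 (-1.71) and the zinc finger gene ZIK1 (-1.70). In both directions the 2 KO libraries lay beyond the 2 WT libraries at each of these genes. CD24, ITGA11, CAMK2N1, SRM, ZSCAN18, EPS8L1, TBL2 and ZIK1 passed the threshold once both KO libraries numbered 1 were left out (41 promoters in all, 22 higher and 19 lower, with the WT mock pair as the only source of spread). TBL2 also passed without KO mock replicate 1 alone (adjusted p = 0.0361). The alternative without both libraries was chosen after the data were seen, and PCAT5 missed the threshold there (adjusted p = 0.0543).

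The lower promoters lay together on the chromosomes. In 6 regions the signal 50 to 100 kb away from TSSs was lower in KO than in WT: 63.1 to 77.3 Mb and 105.3 to 158.9 Mb of chromosome 7, 33.9 to 38.5 Mb of chromosome 10, 51.1 to 53.2 Mb and 54.7 to 58.6 Mb of chromosome 19, and 0.0522 to 30.4 Mb of chromosome 20. They held 214 (4.23%) of the tested promoters and 54 (87.1%) of the 62 with an unadjusted p under 0.05 on the lower side, PCAT5, EPS8L1, TBL2, ENSG00000238176 and ZIK1 among them, and also ZSCAN18 on the higher side. With each window taken over the distal signal around the same site, the log2 difference of PCAT5 was -0.07, that of EPS8L1 -1.10, of TBL2 -1.20, of ZIK1 -1.03, of ENSG00000238176 0.29 and of ZSCAN18 2.09. In 2 regions, 3.54 to 31.9 Mb of chromosome 10 and 35.0 to 40.4 Mb of chromosome 19, distal signal was higher in KO. The median log2 difference was -0.70 for promoters of the lower regions, 0.56 for those of the higher regions and 0.11 elsewhere.

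**Figure D3:**
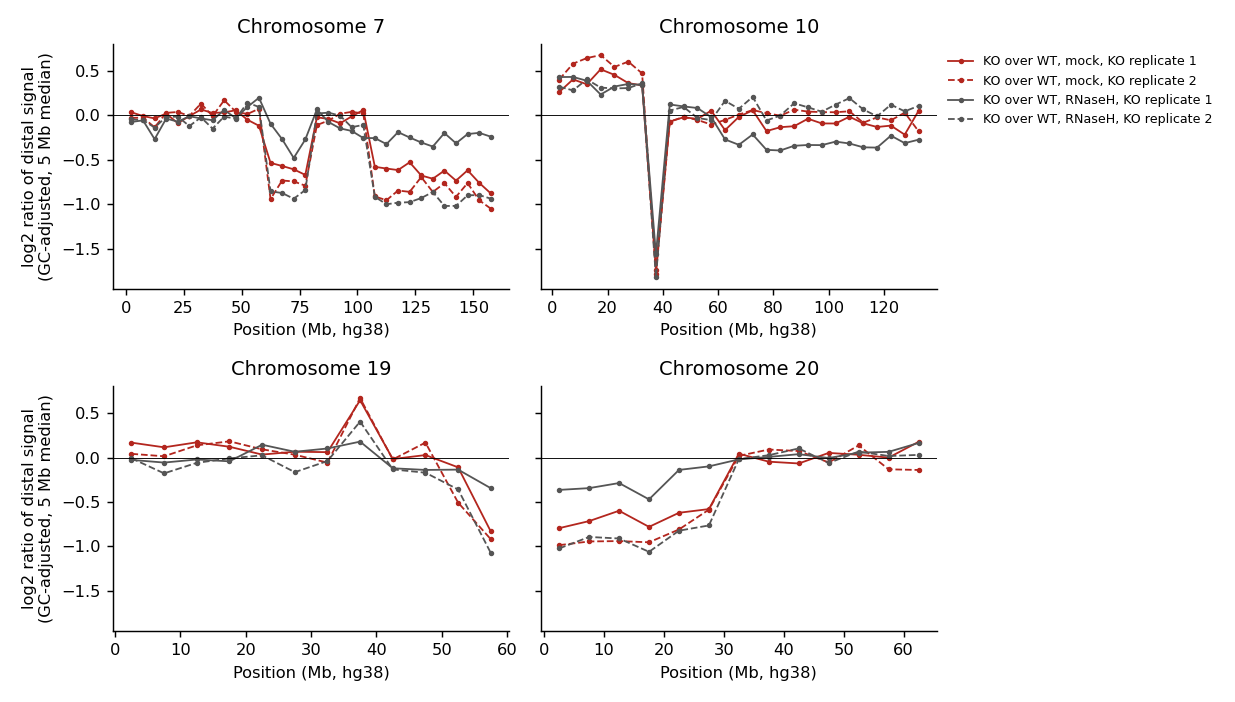
Log2 ratio of KO over WT signal 50 to 100 kb away from start sites, adjusted for GC content and taken as medians of 5 Mb, along chromosomes 7, 10, 19 and 20, for the 4 KO libraries, each over a WT library of the same treatment. In the lower regions the medians were -0.70 and -0.89 in the mock libraries and -0.27 and -0.95 in the RNaseH libraries of replicates 1 and 2.

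Genes often used as R-loop loci in DRIP-qPCR gave 5 tested promoters, none of which passed in KO against WT. Promoter signal of MYC, the growth-promoting transcription factor, was 12.9 in WT mock and 22.0 in KO mock (log2 0.86), and that of CCND1, cyclin D1, 24.9 and 40.6 (0.76). BAMBI, a pseudoreceptor of the TGF-beta family, had 1.55 and 3.26 (1.08, the smallest unadjusted p of the list, 0.0247), EGR1 46.4 and 46.9 (0.05), and ING3 0.934 and 0.576 (-0.67). BAMBI lies in the higher region of chromosome 10 and ING3 in a lower region of chromosome 7, and over their own distal signal they stood at 0.78 and -0.19. EGR1 turned to a log2 of -0.27 without WT mock replicate 1. Each of the 5 had adjusted p = 0.999.

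No gene list passed in KO against WT, by camera with its preset correlation, with an estimated correlation (smallest adjusted p = 0.815) or by fry (0.717), over 14 lists. Genes of cytosolic ribosomal proteins had the smallest camera p among the lists with a positive median: 13 of 14 promoters lay above 0, with a median log2 of 0.43 (camera adjusted p = 0.112). At an unadjusted camera p under 0.05 there were 2 lists, this one and genes of other cell types. RPL27 (1.03, but -1.39 in the narrower window) and RPS7 (0.84) had the smallest p of that list. Genes of other cell types that should be silent here had a median of -0.18 (camera adjusted p = 0.112), with NEUROD2, a neuronal transcription factor, at -0.91 and CD79A, a B cell receptor component, at -0.63. CD79A turned to 0.57 without KO mock replicate 2. Without KO mock replicate 1, camera called ribosomal proteins (median 0.87, adjusted p = 0.000286) and DNA replication factors (0.51, adjusted p = 0.0233) as higher and the silent genes as lower (-0.45, adjusted p = 0.000135), and with an estimated correlation each had adjusted p = 0.830. Without WT mock replicate 2 it called ribosomal proteins (0.75, adjusted p = 0.0125), with adjusted p = 0.974 by an estimated correlation. Without both KO libraries numbered 1, where the WT mock pair alone gives the spread, the 3 lists were called again, at 0.000286, 0.0234 and 0.000135, each with adjusted p = 0.831 by an estimated correlation.

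In the other lists no promoter passed over all genes. Adjusted over the list alone, 1 passed: CALD1, the actin-binding caldesmon, fell by 1.47 in the list of extracellular matrix and mesenchymal genes (median 0.27), and it lies in a lower region of chromosome 7 (-0.85 over its own distal signal). The median was 0.31 for DNA replication factors, where MCM10, a factor of origin firing, stood at 1.30 in a higher region (0.75 over its own distal signal) and the helicase subunit MCM5 at 0.72. It was 0.41 for the integrated stress response (CEBPG 0.81, PSAT1 0.70), 0.29 for p53 targets (BAX 0.74, PMAIP1 0.60) and 0.21 for heat shock genes (BAG3 0.67, HSPH1 0.23). Immediate early genes had 0.20 (FOSB -0.57), spliceosome and hnRNP genes 0.20 (SRSF7 0.76, HNRNPC -0.67), oxidative phosphorylation 0.15 (ATP5F1D 0.99, COX7A2 -0.67) and R-loop processing factors 0.13. In that last list RNASEH2A, the catalytic subunit of RNase H2, had 1.1 in WT mock and 2.88 in KO mock (1.31), and the helicase DDX21 0.64. Cilium genes had a median of -0.06, or 0.06 over their own distal signal (DYNC2I1, a dynein-2 intermediate chain in a lower region, -1.15, or -0.38 over its own distal signal, and BBS10 -0.81), and cholesterol synthesis genes -0.01 (SC5D -0.24, MSMO1 0.23). MSMO1 turned to -0.30 without WT mock replicate 1 and HSPH1 to -0.06 without KO mock replicate 2. Under quantile normalization the medians of extracellular matrix, heat shock and immediate early genes were -0.08, -0.08 and -0.15, and flank scaling put that of cholesterol synthesis at 0.04.

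At termination sites no difference in the mean was resolved: 1.12 ± 0.197 (SD, n = 2) in WT mock and 1.24 ± 0.225 (SD, n = 2) in KO mock, a log2 of 0.15 (exact permutation p = 0.667) that turned to -0.02 without WT mock replicate 1 and to -0.05 without KO mock replicate 2, and was 0.14 and 0.15 within replicates 1 and 2. Of 4585 TTSs, 3 fell and none rose in limma, all 3 inside the lower regions. At RNF24, a membrane-bound RING finger gene, signal fell from 6.96 ± 3.08 to 0.842 ± 0.00068 (log2 -2.90, adjusted p = 1.52e-05), on chromosome 20 at position 3927309. PCAT5 fell by 2.55 (adjusted p = 0.000420) and ENSG00000226578, on chromosome 10, by 2.12 (adjusted p = 0.0219). The highest positive differences, LINC00452 (1.95, adjusted p = 0.0595), KPNA7, an importin (1.55), and CPNE7, a copine (1.46), did not pass. At an unadjusted p under 0.05 there were 51 higher and 72 lower TTSs, together below the share that this threshold gives by chance. With 1 library left out the count ranged from 1, without WT mock replicate 1 (where RNF24 remained) or replicate 2 (where PCAT5 remained), to 5, without KO mock replicate 1 or either KO RNaseH library. RNF24 lost its call without WT mock replicate 2 (adjusted p = 0.295), PCAT5 without WT mock replicate 1 (0.942), and ENSG00000226578 without either of them (0.775 and 1.00) or KO mock replicate 2 (0.749). LINC00452 passed as higher without either KO RNaseH library (adjusted p = 0.0364).

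At replication origins no difference in the mean was resolved either, with 1.14 ± 0.108 (SD, n = 2) in WT mock and 1.13 ± 0.148 (SD, n = 2) in KO mock (log2 -0.01, exact permutation p = 1). It turned to 0.09 without WT mock replicate 1 and to 0.12 without KO mock replicate 2, and was 0.03 and -0.05 within replicates 1 and 2. A few extreme origins weigh on this mean: 1 of them held 28.5% of the summed signal of WT mock replicate 1. Leaving out the highest 1% of origins gave 0.716 and 0.826 in WT mock replicates 1 and 2, and 0.761 and 0.887 in KO mock. An origin at position 795001 of chromosome 16, within 10 kb of RPUSD1, of CHTF18, a subunit of an alternative clamp loader, and of GNG13, rose from 7.96 ± 2.50 to 22.2 ± 4.93 (log2 1.49, adjusted p = 0.0206). Of the 6 origins that fell among 1946, 4 lie in the lower region of chromosome 10: at 34815501, within 10 kb of the polarity gene PARD3 (-1.92, adjusted p = 0.000187), at 35243251, within 10 kb of CCNY, cyclin Y (-2.01, adjusted p = 0.000175), at 35608501, in GJD4, a connexin (-1.85, adjusted p = 0.000332), and at 36881501 (-1.91, adjusted p = 0.000187). The other two, at 38823001 of chromosome 10 (-1.95) and 143264751 of chromosome 1 (-1.78), had overlapping libraries, with 11.6 ± 10.7 against 3.13 ± 3.14 and 97.5 ± 87.7 against 92.3 ± 127. Over their own distal signal the origins at 34815501, 35243251 and 36881501 stood at 0.33, 0.04 and 0.03. All 6 were also lower in KO RNaseH than in the 1 WT RNaseH library. The log2 was -2.43 at 34815501, -2.03 at 35243251, -2.01 at 35608501, -1.96 at 36881501, -3.87 at 38823001 and -3.08 at 143264751. Mock differed little from RNaseH at 35243251, 35608501 and 36881501 (log2 -0.07, -0.12 and -0.25 in WT, -0.06, 0.04 and -0.20 in KO). The origin of chromosome 16 was not higher in KO RNaseH (-0.85). The origin of chromosome 16 lost its call without WT mock replicate 1 (adjusted p = 1.00), WT mock replicate 2 (0.0718) or KO mock replicate 2 (1.00), and that by PARD3 without WT mock replicate 2 (0.0868). The count of 7 became 0 without WT mock replicate 1, 4 without KO mock replicate 2 and 14 without KO mock replicate 1. At an unadjusted p under 0.05 there were 47 higher and 38 lower origins, together slightly below the share that this threshold gives by chance.

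The next comparison, mock against RNaseH in KO cells, asks where the signal was sensitive to RNase H1. FASN, fatty acid synthase, stood at 55.4 ± 7.45 (SD, n = 2) in KO mock and 1.71 ± 0.727 (SD, n = 2) in KO RNaseH (log2 5.03, adjusted p = 4.35e-22), on chromosome 17 at position 82098333. The transcription factor KLF2 stood at 35.8 ± 1.31 and 1.24 ± 0.829 (4.96), CALM2, a calmodulin gene, at 29.1 ± 11.4 and 0.888 ± 0.389 (4.95), and FOS, a subunit of AP-1, at 27.4 ± 4.51 and 0.951 ± 0.656 (4.93). EGR1, an immediate early transcription factor, stood at 46.9 ± 0.861 and 1.75 ± 1.02 (4.82). CCDC9B (4.99), MYH9-DT, a transcript divergent from the myosin gene MYH9 (4.74), ENSG00000279821 (4.56) and HNRNPF, an RNA-binding protein (4.55), were also among the 10 highest. All of these also passed as higher in WT mock than in WT RNaseH, as with FASN at 27.0 ± 8.08 and 3.21 (3.02), FOS at 31.1 ± 3.59 and 5.50 (2.48) and EGR1 at 46.4 ± 14.5 and 4.97 (3.17).

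Over the 5060 promoters kept for a mean above distal signal, 1389 were higher and 6 lower in KO mock than KO RNaseH, with a median log2 of 0.51. Over their own distal signal 1075 were higher and 635 lower, with a median of 0.18. Over all 9879 TSSs, tested or not, the median signal was 0.524 and 0.531 in KO mock replicates 1 and 2, and 0.729 and 0.514 in KO RNaseH. Mean promoter signal was 1.22 in KO mock and 0.659 ± 0.176 (SD, n = 2) in KO RNaseH, a 1.84-fold difference. The KO mock mean of both libraries was 1.55 times KO RNaseH replicate 1 and 2.27 times KO RNaseH replicate 2. Within replicate 1 the signal was 1.13 in mock and 0.783 in RNaseH, and within replicate 2 it was 1.30 and 0.535. The count was 866 without KO mock replicate 2 and 865 without KO RNaseH replicate 2, and 1869, of which 1344 were shared, without both KO libraries numbered 1. Quantile normalization, which gives every library the same distribution and so moved the median by a log2 of -0.35, left 1. Among the lower promoters whose libraries did not overlap, BPIFB2 had a log2 of -1.41 (0.351 ± 0.191 in KO mock and 1.00 ± 0.398 in KO RNaseH), ENSG00000279628 -1.30 and the citrate transporter SLC13A5 -1.25 (adjusted p from 0.0158 to 0.0373). In WT all 3 missed the threshold. Without KO mock replicate 2 all 3 lost their call (adjusted p = 0.336, 0.132 and 0.0847), and BPIFB2 lost it without KO RNaseH replicate 1 (0.139) too. The other two also lost it without KO mock replicate 1 (0.0915 and 0.198) or either WT mock library (0.0534 and 0.0682), ENSG00000279628 without KO RNaseH replicate 1 (0.203) and SLC13A5 without KO RNaseH replicate 1 (0.0663) or 2 (0.0599).

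**Figure D4:**
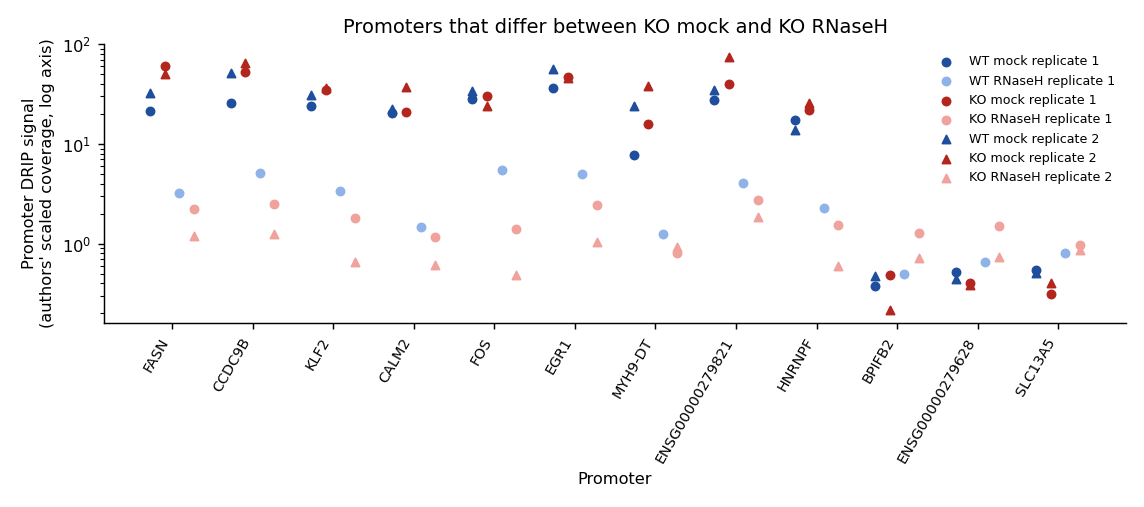
Promoter signal (log axis) of each library at 9 promoters higher and 3 lower in KO mock than in KO RNaseH. FASN stood at 55.4 in KO mock and 1.71 in KO RNaseH.

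Immediate early genes, the first to be transcribed after a stimulus, made up the list with the smallest camera p in mock against RNaseH. In KO cells 12 of its 13 tested promoters were higher in mock (12 also adjusted over the list alone), with a median of 3.53, among them MCL1 (3.78), DUSP5 (3.53) and KLF4 (2.20), and EGR2 alone did not pass (0.16). Camera gave the list adjusted p = 1.70e-19, and with an estimated correlation adjusted p = 0.394. In WT cells 11 passed (12 adjusted over the list alone), with a median of 2.21 and camera adjusted p = 3.12e-16 (0.503 as the adjusted p with an estimated correlation). Of the 5 DRIP-qPCR loci, MYC (3.76), CCND1 (4.14), BAMBI (1.98) and EGR1 passed in KO and ING3 (0.12) did not, and 3 passed in WT. Camera gave adjusted p = 4.29e-06 in KO, with an estimated correlation adjusted p = 0.523. ING3 turned to -0.19 without KO mock replicate 2 and to -0.28 without KO RNaseH replicate 2.

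Camera also called genes of 4 other groups as higher in mock in KO cells. Of 14 ribosomal protein genes, 12 passed (12 adjusted over the list alone; median 2.27), such as RPL27 (3.82) and RPS7 (3.16), with camera adjusted p = 4.29e-06 and, with an estimated correlation, adjusted p = 0.523. Of 15 spliceosome and hnRNP genes, 8 passed (10 adjusted over the list alone; median 1.70), SRSF6 at 4.36 among them, with camera adjusted p = 0.000160 (adjusted p = 0.523 with an estimated correlation). Of 12 extracellular matrix and mesenchymal genes, 10 passed (10 over the list alone; median 1.99), such as LGALS1, galectin-1 (2.93), COL12A1, a collagen, and FSTL1 (2.7 each), with camera adjusted p = 8.99e-05 (adjusted p = 0.523 with an estimated correlation). Of 12 oxidative phosphorylation genes, 5 passed (5 over the list alone; median 0.93), COX7C at 4.42 among them, with camera adjusted p = 0.0471 (adjusted p = 0.664 with an estimated correlation). That last call was lost without KO mock replicate 2 (adjusted p = 0.0865), KO RNaseH replicate 1 (0.0770) or KO RNaseH replicate 2 (0.0652), under distal scaling (0.0607) and over their own distal signal (median 0.37, adjusted p = 0.413). Quantile normalization ended the camera calls of ribosomal proteins (median 0.63, adjusted p = 0.115), spliceosome and hnRNP genes (0.56, adjusted p = 0.115), extracellular matrix genes (0.32, adjusted p = 0.915) and the DRIP-qPCR loci (0.77, adjusted p = 0.115). It left the camera calls of immediate early genes (median 1.32, adjusted p = 0.00688) and oxidative phosphorylation genes (0.68, adjusted p = 0.0337). With an estimated correlation both of those had camera adjusted p = 0.421. By fry, which asks whether a list moves one way on balance, immediate early genes had adjusted p = 0.0286, and these 4 lists, heat shock genes and the DRIP-qPCR loci had 0.0330 to 0.0416. None of them passed by fry without KO mock replicate 1 (smallest adjusted p = 0.0864), KO mock replicate 2 (0.139) or either WT mock library (0.0964).

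In the remaining lists camera made no call in KO mock against KO RNaseH. All 4 heat shock genes passed (median 1.85, camera adjusted p = 0.0707), a list that camera called without KO mock replicate 1 (adjusted p = 0.0397, and adjusted p = 0.489 with an estimated correlation) or under distal scaling (adjusted p = 0.0424, and adjusted p = 0.357 with an estimated correlation). Of 9 R-loop processing factors 5 passed (7 adjusted over the list alone; median 1.42), among them RNASEH2A at 1.79, RNASEH2B at 1.46, DDX17 at 1.88 and DDX21 at 1.94, while AQR (-0.56) and DHX9 (1.15) did not. Of 14 replication factors 5 passed (median 0.67), of 13 integrated stress response genes 3 (0.87; PPP1R15A 3.99, CEBPG 1.98, CHAC1 1.25), and of 8 p53 targets 4 (0.90; PLK2 3.37, BAX 2.31). Of 11 cilium genes 2 passed (0.60; IFT22 1.73, IFT81 2.34), of 3 cholesterol synthesis genes 1 (0.58), and of 13 genes of other cell types 2 (0.34; OPN1SW, a cone opsin, 3.26 and CD79A 1.79).

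Mock against RNaseH in WT cells asks the same of the parental line, with 2 libraries against 1. Of the 5060 promoters 219 were higher in mock and none lower, with 46 lower at an unadjusted p under 0.05. The mean over all TSSs was 1.04 in mock and 0.786 in RNaseH, 1.33-fold. The median over all TSSs went the other way, with 0.524 and 0.572 in the WT mock libraries and 0.654 in WT RNaseH. Besides immediate early genes, camera called ribosomal proteins (1 of 14 passed, 4 adjusted over the list alone; median 1.1, adjusted p = 0.000116), the DRIP-qPCR loci (2.11, adjusted p = 0.000109), spliceosome and hnRNP genes (4 of 15, 6 over the list alone; 1.08, adjusted p = 0.000109) and extracellular matrix genes (2 of 12, 4 over the list alone; 1.20, adjusted p = 0.00662). With an estimated correlation each of these 4 had adjusted p = 0.604, and by fry none of the 14 lists passed (smallest adjusted p = 0.181). The count was 60 without WT mock replicate 1 and 41 without WT mock replicate 2, and none passed under quantile normalization or with no filter. Over their own distal signal 255 were higher and 132 lower. Quantile normalization also ended the camera calls of ribosomal proteins (median 0.35), the DRIP-qPCR loci (0.43), spliceosome and hnRNP genes (0.51) and extracellular matrix genes (-0.06), with adjusted p of 0.0786 or more. It made genes of other cell types a call as lower (-0.57, adjusted p = 0.0440, and adjusted p = 0.693 with an estimated correlation), and distal scaling made heat shock genes one as higher (1.31, adjusted p = 0.0485, and adjusted p = 0.351 with an estimated correlation).

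The difference between KO and WT in the response to RNase H1 was tested as an interaction, and no promoter passed in limma (smallest adjusted p = 0.875). At an unadjusted p under 0.05 there were 263 promoters with the larger mock to RNaseH ratio in KO and 6 with the larger ratio in WT, and the median over all promoters was 0.47. That median was 0.12 under quantile normalization and 0.17 with each window over its own distal signal, with 56.4% and 59.9% of promoters above 0 where there were 77.5%. RNASEH2A (1.97), ZSCAN18 (1.78) and ITGA11 (2.31) stood among those 263.

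Between the RNaseH libraries themselves, FOS was the single promoter that passed, lower in KO by a log2 of -2.63 (adjusted p = 0.0400), with 5.50 in WT RNaseH and 0.951 ± 0.656 (SD, n = 2) in KO RNaseH. At an unadjusted p under 0.05 there were 22 higher and 411 lower promoters in KO RNaseH, and the median was -0.38 (-0.11 under quantile normalization and -0.12 over their own distal signal). Mean promoter signal was 0.786 in WT RNaseH, 0.783 in KO RNaseH replicate 1 and 0.535 in KO RNaseH replicate 2. The FOS call was lost, with 0 promoters called, without KO RNaseH replicate 2 or without any 1 of the 4 mock libraries. It was also lost under every other scaling, pseudocount, filter and window, with trend and robust, and with only the groups compared.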

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

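All tests in this part were chosen after the results were seen, except that of a general gain in contrast and that of lower depth.

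At 4 of the named promoters every library moved one way between mock and RNaseH in WT and the other way in KO. In WT the direction rests on 1 RNaseH library. ZSCAN18 stood at -0.18 in WT and 1.60 in KO (difference 1.78, unadjusted p of 0.0196), and RNASEH2A at -0.18 and 1.79 (1.97, unadjusted p of 0.00956). At RNASEH2A WT mock replicate 2 (1.246) lay barely under WT RNaseH (1.255), with WT mock replicate 1 at 0.972. PSAT1 stood at -0.34 and 1.02 (1.36, unadjusted p of 0.0745) and BBS10 at 0.24 and -0.42 (-0.66, unadjusted p of 0.388). By the interaction term of limma none passed (adjusted p = 0.875 for ZSCAN18, RNASEH2A and PSAT1, and 0.928 for BBS10). The same held for 259 (5.12%) of the 5060 promoters, while at 2029 (40.1%) both genotypes moved the same way.

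Windows lower in KO lay together on a few chromosome arms. GC content is argued against, since at TSSs of other chromosomes with the same GC content the unadjusted distal signal had a median log2 of 0.10 and 0.083 in the mock libraries of replicates 1 and 2 (bootstrap SE 0.010), against -0.66 and -0.82 in the lower regions. A loss of hybrids at the sites alone was not decided, since the regions were chosen for lower distal signal, by which each promoter was then divided. Over their own distal signal the promoters there had a median of 0.030 (bootstrap SE 0.034) against -0.70 before, so they were about as low as their surroundings. A difference in copy number between the WT and KO cultures may account for the pattern, because distal signal was also lower in the RNaseH libraries, by a median of -0.27 in replicate 1 and -0.95 in replicate 2. Copy number stays open since the pooled median of replicate 1 fell short of the bound set for the test. The regions differed in this. At 33.9 to 38.5 Mb of chromosome 10 (10 TSSs) the RNaseH shifts were -1.56 and -1.59 in replicates 1 and 2. They were nearly as deep as those in mock, -1.70 and -1.67. In the other lower regions the RNaseH shift of replicate 1 ran from -0.33 to -0.17. An effect of CFAP20 loss on these chromosome arms stays open as untested.

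Promoter signal was higher in KO mock than in WT mock within each replicate number, by 1.18-fold in the first and 1.15-fold in the second. The authors' scaling factors stay open as its source: with each library over its median distal signal the mean log2 was 0.27 against 0.22 before (SD between replicates 0.16), while over its mean distal signal it was 0.085, under the bound set for the test. A general gain in contrast between strong and weak windows may account for part of it, because windows away from TSSs with the same mean signal stood at 0.22 and 0.12 where the promoters stood at 0.32 and 0.23. The promoters exceeded them by 0.099 and 0.109 (bootstrap SE 0.014), 1 value on each side of the bound set beforehand, so this stays open. More hybrids at promoters on loss of CFAP20 stays open as well, untested apart from this.

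In the lower regions of chromosomes 7, 19 and 20 the shift in distal signal was shallower in both KO libraries numbered 1 than in those numbered 2, unlike that of chromosome 10 (-1.70 and -1.67 in mock). Lower depth is argued against for KO RNaseH replicate 1, since from means of signal, which depth does not shift, the step there was 0.278 times that of replicate 2. WT DNA mixed in is argued against for that library, since at 33.9 to 38.5 Mb of chromosome 10, where WT stood at 1.65 to 1.94, KO RNaseH replicate 1 lay only 0.022 above replicate 2. If the shifts are copy number, which stays open, DNA of cells that lack them and the higher signal of chromosome arm 10q (0.44 to 0.53 in WT) could be mixed in: the share of KO DNA estimated from 10q and from the lower signal of chromosomes 7 and 20 differed by at most 0.079, with 0.685 and 0.763 for KO mock replicate 1 and 0.256 and 0.326 for KO RNaseH replicate 1. No biological explanation was tested, as the design gives no group that parts these libraries.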

How the results depend on the processing

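The alternatives that combine distal scaling with the block, take each window over its own distal signal, leave out both KO libraries numbered 1, subtract RNaseH without KO RNaseH replicate 2, leave out the shifted regions or use the origins of the coordinate table alone were chosen after the data were seen. The difference between quartiles of transcription kept its direction in all 10 alternatives (0.11 to 0.55 with a library left out). Unless a reason is given, the cause was not tested.

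Site means, KO mock over WT mock, as log2. The median over sites gave -0.055 at promoters and -0.10 at TTSs, where the mean gave 0.22 and 0.15. With RNaseH signal subtracted the promoter value was 1.10, the TTS value 0.765 and the origin value 4.26, and without KO RNaseH replicate 2 they were 0.738, 0.523 and 1.33; the subtracted origin signal in WT is close to 0, which makes the ratio large. The origin value of -0.01 turned to 0.024 under distal scaling, 0.039 in the narrower and 0.072 in the wider window, 0.096 without the highest 1% of origins, 0.0047 with distal scaling and the replicate block (-0.011 with the block alone), 0.00035 without the shifted regions and 0.056 for the origins of the coordinate table. With 1 library left out the ranges were 0.10 to 0.35 at promoters, -0.051 to 0.34 at TTSs (below 0 without WT mock replicate 1 or KO mock replicate 2) and -0.15 to 0.12 at origins.

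Calls, KO mock against WT mock. The 1 promoter became 0 under distal scaling, quantile normalization, a pseudocount 10 times as large, no filter, a filter at 2 times the distal signal, the narrower window, only the groups compared and each window over its own distal signal. It became 7 in the wider window, 2 with the replicate block, 3 with distal scaling and the block, and 41 without both KO libraries numbered 1, and it was 0 to 1 with a library left out. The 3 TTSs became 1 under distal scaling, 0 under quantile normalization, 0 with no filter, 1 in the narrower and 5 in the wider window, 5 with the replicate block, 5 with only the groups compared, 10 with distal scaling and the block, 0 over their own distal signal, 7 without both KO libraries numbered 1 and 1 to 5 with a library left out. The 7 origins became 4 under distal scaling, 0 under quantile normalization, 14 with no filter, 4 with the stricter filter, 1 in the narrower window, 0 over their own distal signal, 33 without both KO libraries numbered 1, and 0 (without WT mock replicate 1) to 14 (without KO mock replicate 1) with a library left out. The loss of calls over their own distal signal follows from its construction where the distal signal differs. The 0 gene lists became 3 without both KO libraries numbered 1 and were 0 to 3 with a library left out (3 without KO mock replicate 1, 1 without WT mock replicate 2).

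Calls, mock against RNaseH and between RNaseH libraries. The 219 WT promoters became 429 under distal scaling, 0 under quantile normalization, 340 with the larger pseudocount, 0 with no filter, 76 in the narrower window, 97 with trend and robust, 566 with only the groups compared, 629 with distal scaling and the block (187 with the replicate block alone), 387 over their own distal signal, 566 without both KO libraries numbered 1, and 41 (without WT mock replicate 2) to 291 with a library left out, with 60 without WT mock replicate 1. The 1395 KO promoters became 1 under quantile normalization, which removes the difference in distribution between mock and RNaseH, 799 with no filter, 2124 with distal scaling and the block, and 865 (without KO RNaseH replicate 2; 866 without KO mock replicate 2) to 1664 with a library left out. Over their own distal signal 1710 passed, 635 of them lower in mock. The 1 promoter between RNaseH libraries became 0 under distal scaling, quantile normalization, either other pseudocount, no filter, the stricter filter, both other windows, trend and robust, the replicate block, only the groups compared, distal scaling with the block and own distal signal, 557 without both KO libraries numbered 1, and was 0 to 1 with a library left out. The 0 interaction calls became 130 without both KO libraries numbered 1 and stayed at 0 in the other 19.

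Named genes and origins. Of 1403 alternatives of 68 results, 1250 kept direction and side of the threshold, 109 lost the threshold, 24 gained it and 20 reversed. EGR1 in KO against WT was -0.69 under quantile normalization and -0.11 in the wider window, and -0.27 to 0.37 with a library left out (lowest without WT mock replicate 1). MSMO1 was -0.011 under quantile normalization, -0.0060 in the narrower and -0.0059 in the wider window, and -0.30 to 0.75 with a library left out (lowest without WT mock replicate 1). HSPH1 was -0.037 under quantile normalization and -0.056 to 0.51 with a library left out (lowest without KO mock replicate 2). CD79A was 0.64 in the wider window and -1.82 to 0.57 with a library left out (highest without KO mock replicate 2). In the narrower window SC5D was 0.025, RPL27 -1.39 and COX7A2 0.071. Over their own distal signal ENSG00000238176 was 0.29 and the origins of chromosome 10 at 35243251, 34815501 and 36881501 were 0.041, 0.33 and 0.034. ING3 in KO mock against KO RNaseH was -0.28 to 0.52 with a library left out (below 0 without KO mock replicate 2 or KO RNaseH replicate 2).

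With the libraries of 1 number treated as a replicate block, deviations of replicates correlated at 0.26 between WT mock and KO mock promoters, and the block gave the promoter mean a log2 of 0.22 and called 2 promoters, both lower, EPS8L1 (adjusted p = 0.0365) now among them, and 5 TTSs, 1 higher (LINC00452, adjusted p = 0.0327) and 4 lower. With distal scaling added it also called CD24 as higher (adjusted p = 0.0126) and KPNA7 as a higher TTS (0.0320). At this number of libraries, 9% of 2-fold and 80% of 4-fold changed promoters were called in KO mock against WT mock on simulated data. The simulated noise had the same SD in every window, and other numbers of libraries were not simulated. Leaving out both KO libraries numbered 1 leaves 1 residual degree of freedom, from the WT mock pair, and 1 library in each other group, so the 557 and 130 promoters set single libraries against the spread of that pair. In the shallowest library 30.7% of TSS bins were at 0, and detection by coverage was not tested.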

Other observations

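Gene groups with fewer than 3 tested promoters gave single values. Of 20 glycolysis genes 2 were tested: PGAM1, a phosphoglycerate mutase, had a log2 of 0.90 in KO mock against WT mock and of 2.39 in KO mock against KO RNaseH (adjusted p = 9.21e-06), and LDHB, a lactate dehydrogenase subunit, 0.86 and 3.12 (adjusted p = 3.52e-09). Of 29 genes of common fragile sites, which are mostly very long, 1 was tested: PARD3B, at -0.37 in KO against WT and 1.04 against RNaseH (adjusted p = 0.0955). None of 47 replication-dependent histone genes passed the filter, with H3C6 and H4C8 measured below it, and none of 20 snoRNA host genes was among the measured genes.

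Termination sites kept for a mean above distal signal also had higher signal in mock than after RNase H1. Over all 9879 TTSs, tested or not, the median did not. In WT it was 0.491 and 0.536 in mock replicates 1 and 2 and 0.614 in RNaseH. In KO it was 0.452 and 0.508 in mock replicates 1 and 2, and 0.677 and 0.508 in RNaseH. In KO cells 1420 of 4585 TTSs were higher and 5 lower in mock, led by CPTP, a ceramide-1-phosphate transfer protein (37.6 ± 2.29 in mock and 1.05 ± 0.758 in RNaseH, log2 5.28), PUF60, a splicing factor (65.4 ± 15.1 and 1.93 ± 1.20, log2 5.17), and TALDO1, transaldolase (38.6 ± 7.11 and 1.31 ± 0.683, log2 4.90). The 3 lowest were LACRT (-1.46), ENSG00000265927 (-1.25) and ENSG00000273489 (-1.22). In WT cells 263 TTSs were higher in mock and none was lower in limma, with 28 lower at an unadjusted p under 0.05. Over their own distal signal the median log2 of TTSs went from 0.56 to 0.24 in KO and from 0.32 to 0.18 in WT, and under quantile normalization to 0.20 and 0.08. At origins 630 were higher in KO mock than KO RNaseH and none lower, with 0 lower at an unadjusted p under 0.05 in limma, and in WT 103 were higher and 2 lower. The median at origins, with each taken over its own distal signal, went from 0.54 (86.1% above 0) to 0.04 (52.5%) in KO and from 0.22 (68.2%) to -0.03 (48.8%) in WT, and under quantile normalization it was 0.15 (61.2%) and 0.05 (55.1%). Mean origin signal was 1.13 in WT RNaseH, 1.14 in WT mock and 0.844 ± 0.355 in KO RNaseH. Without the highest 1% of origins it was 0.687 in WT RNaseH and 0.716 and 0.826 in the WT mock libraries. Over all 4784 origins, tested or not, the median was 0.501 and 0.571 in WT mock replicates 1 and 2 and 0.605 in WT RNaseH. In KO the median was 0.493 and 0.562 in mock replicates 1 and 2, and 0.686 and 0.521 in RNaseH. A single origin at position 49156751 of chromosome 4 held 28.5% of the summed origin signal of WT mock replicate 1. Its signal was 1659 and 582 in WT mock replicates 1 and 2, and 1398 and 124 in KO mock replicates 1 and 2. It was 1596 in WT RNaseH, and 1361 and 238 in KO RNaseH replicates 1 and 2.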
